A study of Mus musculus with 12 samples.

How the data were processed

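RNA from mouse hepatic stellate cells was measured on 12 single-colour Illumina BeadChip arrays. Per the labels, cells came from mice with a floxed Pdgfrb gene, either carrying a Cre transgene driven by the GFAP promoter (knockout) or lacking it (wild type), and were cultured and then given PDGF-B at 10 ng/ml or vehicle in medium without serum. The grouping follows the labels, which give genotype and ligand for each sample, and puts 3 arrays in each of 4 groups. Each sample title holds a code, such as P524 or P11, shared by 1 array with ligand and 1 without. There are 6 such codes, 3 per genotype, and cells sharing one are called a preparation here. The labels do not say whether a code stands for an animal, a pool of animals or a culture, so p-values measure the spread between these samples, part of which may be technical.

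The authors deposited a table of probe intensity per array before normalization, on a linear scale and without background subtraction, and this table was the start of the work. A second table holds the authors' normalized intensity. Its columns have medians near 90.9 and rank correlations near 0.99999 with the same arrays of the first table, and its scale is linear with no centring. How it was normalized, and which scanner software summarised the beads, is not given in the sources used here. The arrays had median intensities of 86.2 to 96.2, and 44.2% to 52.9% of the 45281 probes were above background.

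Intensities were background-corrected with normexp (offset 50), quantile-normalized and taken as log2 values in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 for correlations within preparations. The tables used here held no detection p-values. The design written in advance had allowed for this in the normalization, but gave no substitute for the detection filter. Detection was therefore estimated from the values, by mirroring the part of each array's distribution below its mode to give the background. Probes were kept when this gave p under 0.05 on at least 3 arrays, which left 26234. The annotation gave 1 gene symbol for 34885 probes, several for 18 and listed no gene for 10378, and 0 symbols needed updating through the gene ID. For 34807 probes with 1 symbol the gene ID was found in the RefSeq table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. The brightest kept probe stood for each gene, giving 13277 genes, of which 5498 had more than 1 kept probe.

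Group means were fitted to all arrays together with lmFit and eBayes, which left 8 residual degrees of freedom. The 5 comparisons were ligand against no ligand in wild-type cells, the same in knockout cells, knockout against wild type without ligand and with ligand, and the difference between the genotypes in the ligand response. All adjusted p-values are from limma with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene groups were tested with camera, which asks whether a group shifted relative to all other genes, with an inter-gene correlation preset to 0.01 and adjustment over 39 lists. Of 41 lists written from textbook knowledge, the remainder had fewer than 5 measured genes, and 698 of the 851 list entries were measured. The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined.

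The genes named in the text are a fixed panel (Pdgfrb, Pdgfra, Acta2, Col1a1, Col3a1, Timp1, Des, Ccnd1, Mki67, Fos, Egr1 and Myc), up to 8 genes in each direction with the largest change among those past the threshold whose groups or pairs did not overlap, and up to 4 members with the smallest p of each list described. Where no gene passed, the 5 genes with the smallest p in each direction are named, with provisional names left out. Mki67 was not among the measured genes. Other genes are said to have been chosen after their values were seen.

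Deviations from the group means correlated between the arrays of the same code at r = 0.58 to 0.93 across genes, and each array correlated best with the one sharing its code. The codes were therefore taken to pair the arrays, a pairing that comes from the titles and from this check. The fit without the preparation as a block is the main one, as chosen in advance, and the fit with a block leaves 4 residual degrees of freedom in a ligand comparison.

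Each fit was tested on simulated data of 13277 genes. Changes of 0.5, 1 and 2 on the log2 scale were put into 67, 67 and 66 of them. The spread was drawn for each gene on its own, and a change was the same in every preparation given it. Shifts shared by many genes, or a preparation that responds otherwise, were therefore not simulated. For the ligand response of wild-type cells, the fit without a block recovered 37.3%, 79.1% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 0 false calls among 143, and the blocked fit 98.5%, 100% and 100% with 16 false among 215. For the genotype difference without ligand the fit without a block recovered 49.3%, 83.6% and 97%, with 36 false among 189, and the blocked fit 44.8%, 86.6% and 98.5% with 58 false among 211. For the difference in response the fit without a block recovered 16.4%, 64.2% and 87.9% with 0 false among 112, and the blocked fit 77.6%, 100% and 100% with 11 false among 196. With the preparation as a random block, 82.1%, 100% and 100% were recovered with 3 false among 191 for the ligand response of wild-type cells, and 55.2%, 86.6% and 97% with 4 false among 163 for the difference in response. For the genotype differences the blocked fit is the one with the random block throughout. A fixed block cannot estimate them, since each preparation belongs to a single genotype. The share of false calls lay above the 0.05 that the adjustment aims at in every fit of the genotype difference and in the fixed-block fits of the other comparisons simulated, and below it in their fits with a random block or without a block.

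Alternatives tried were no background correction, median scaling, the authors' normalized values, no filter and a stricter filter on dim probes, the mean of a gene's probes, the preparation as a fixed or random block, only the groups compared, an intensity trend with a robust prior, array weights, an estimated inter-gene correlation, a minimum log2 change of 1 for the genes counted (which gives no p of its own), and leaving out each array and each preparation. The slide could not be used as a block because the sources used here do not give it. Probes without a single symbol (4470 of those kept) were left out of the gene tests.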

Results

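Gene expression was profiled in cultured hepatic stellate cells, the liver pericytes that store vitamin A and turn into matrix-producing myofibroblasts after injury. The cells came from wild-type mice and from mice with a deletion of Pdgfrb, the beta receptor for platelet-derived growth factor. The 12 arrays form 4 groups of 3, wild-type and knockout cells each with and without PDGF-B (10 ng/ml). The design asks what the ligand changes in each genotype, how the genotypes differ with and without it, and whether the response depends on genotype. Values are normalized log2 intensities, and the number of arrays limits their precision.

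Pdgfrb itself, the targeted gene, had a log2 intensity of 7.07 ± 0.60 in knockout and 7.10 ± 0.52 in wild-type preparations (SD, n = 3 each). The difference of -0.03 was smaller than the spread between preparations (exact two-sided permutation test, p = 0.9, where 3 against 3 can give no p below 0.1). Knockout preparations measured 6.47 (P338), 7.07 (P524) and 7.67 (P522), and wild-type preparations 6.75 (P11), 6.85 (P393) and 7.70 (P530). Where the Pdgfrb probe lies relative to the deleted part of the gene is not known here, so its level does not check the genotype labels.

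Markers of several liver cell types were present besides those of stellate cells. Above background on all arrays were 21 of 23 contractile and myofibroblast genes, 9 of 22 genes of quiescent stellate cells, 17 of 21 macrophage genes and 9 of 10 mesothelial genes, against 5 of 22 hepatocyte and 2 of 15 lymphocyte genes. Apart from Acta2, the single genes named in this paragraph were chosen from the marker lists after their values were seen. Upk3b, a uroplakin of mesothelial cells, ranged from 9.34 in preparation P522 to 12.55 in preparation P524, both knockout. Adgre1, the macrophage antigen F4/80, ranged from 10.57 in preparation P524 to 11.93 in preparation P522. Some macrophage genes were about as bright as Acta2 (mean 13.91 over all arrays), such as Lyz2 (13.76) and C1qb (13.03), while Clec4f was at 5.93. Macrophage genes as a list were lowest in P524 and mesothelial and cholesterol synthesis genes in P522, both knockout preparations. Preparations accounted for 88.7% of the variance over all genes, of which 9.39 percentage points lay between the genotypes, and the ligand for 4.07%. These are plain shares of sums of squares. What groups without any effect would take by chance was not removed, so the shares alone show no effect of genotype or ligand. At an adjusted p under 0.05, 6067 genes differed between preparations of one genotype.

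**Figure D1:**
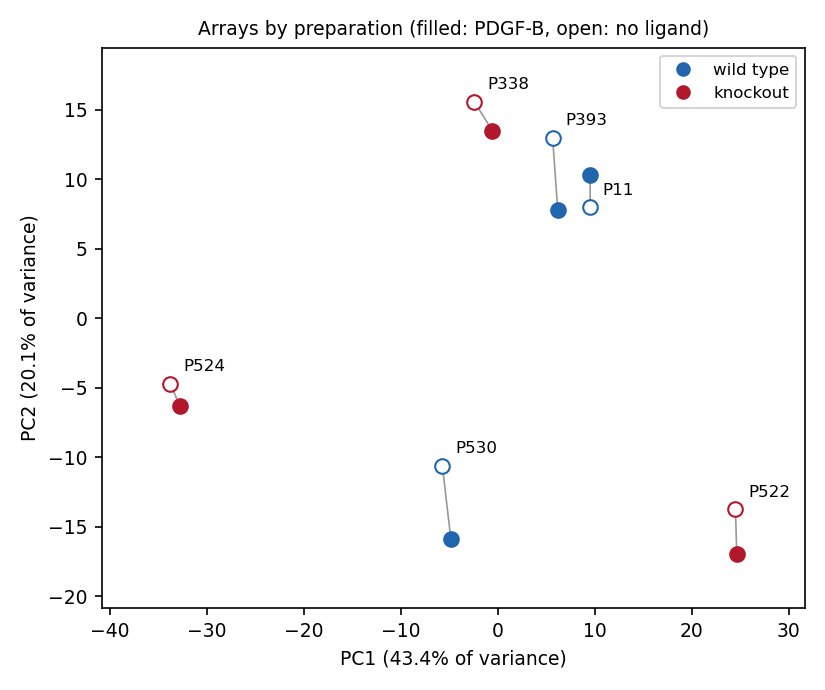
Each point is 1 array placed by its scores on the first (x axis, 43.4% of variance) and the second (y axis, 20.1%) principal component of all 13277 genes, coloured by genotype, filled with PDGF-B and open without, with a line joining the arrays of a numbered preparation. Arrays of the same preparation lie next to each other, and knockout preparations P524 and P522 lie at opposite ends of the x axis.

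Without ligand, knockout cultures had less Cd300ld. It is a receptor of the CD300 family found on myeloid cells, and which of the cultured cells held it was not tested. Its level was 6.37 ± 0.18 in knockout against 9.18 ± 0.24 in wild-type cells (SD, n = 3), 6.97-fold lower (log2 change -2.80 ± 0.21 SE, adjusted p = 0.00162), with no overlap between groups, which chance gives for 10% of unchanged genes. It was the 1 gene past the threshold among 13277, with 200 genes higher and 98 lower at an unadjusted p under 0.05 where chance gives 664. This fit takes arrays of the same preparation as independent. Simulated data gave 36 false among 189 calls for this comparison, and 58 among 211 with the block, so adjusted p-values here can be too small. With the preparation as a block 2 genes were lower, the other being Twistnb, which codes for a subunit of RNA polymerase I (log2 change -1.10, adjusted p = 0.0781 without and 0.0105 with the block, 0.00285 to 1 over all alternatives that gave it a p). Leaving out preparation P11 (adjusted p = 0.0918) or P338 (0.0681) ended the Cd300ld call, with its log2 change at -2.78 and -2.84 and adjusted p at 1.66e-04 to 0.0918 over all alternatives that gave it a p. Without preparation P522 the number of genes called was 3, and without its array with ligand 2. Acta2, the smooth muscle actin of myofibroblasts, differed by -0.25 ± 0.15, Col1a1 by 0.14 ± 0.50, Timp1 by 0.07 ± 0.37 and Pdgfra by -0.28 ± 0.41, none past the threshold.

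As groups, genes of the cell cycle were higher in knockout cells without ligand. Of 29 genes of the G1/S transition and DNA replication 25 had positive differences, among them Mcm2 (0.21 ± 0.08) and E2f1 (0.23 ± 0.11), and the list was higher at adjusted p = 4.64e-04 (adjusted p = 0.757 with an estimated correlation). The lists of mitosis (22 of 24 positive, such as Birc5 at 0.53 ± 0.37, against Plk1 at -0.51 ± 0.33) and cell-cycle histones (10 of 12, such as H2az1 at 0.37 ± 0.14) each had adjusted p = 0.0411 (adjusted p = 0.828 and 0.757 with an estimated correlation). Lower were cholesterol synthesis (16 of 18 negative, such as Nsdhl at -0.63 ± 0.46 and Sqle at -0.56 ± 0.45) and macrophage genes (18 of 19, such as Marco at -0.38 ± 0.17 and Mrc1 at -0.83 ± 0.65), each at adjusted p = 0.0031 (adjusted p = 0.828 and 0.757 with an estimated correlation). Also lower were NF-kappaB targets (15 of 17, adjusted p = 0.00573), such as Tnfaip3 at -0.33 ± 0.13 and Vcam1 at -0.35 ± 0.17, and ERK targets and feedback regulators (14 of 20, adjusted p = 0.0411), such as Dusp6 at -0.37 ± 0.10 and Etv1 at -0.67 ± 0.41. With an estimated correlation 0 of these 7 calls held (adjusted p = 0.757 for NF-kappaB and ERK targets with an estimated correlation). In each list 0 members passed the test over all genes and 0 when adjusted over the list alone. Over preparation means the genotypes overlapped for all 7 lists (exact permutation p = 0.4 to 0.7). Calls ended without preparation P522 for cholesterol synthesis (mean -0.022), without P524 for macrophage genes (-0.014) and NF-kappaB targets (-0.017), and without P530 for G1/S (0.10). They ended without any of P338, P524 and P530 for mitosis (0.099, 0.093 and 0.033) and histones (0.16, 0.17 and 0.072). Leaving out preparation P11 also ended the macrophage (-0.22), NF-kappaB (-0.016), ERK (-0.053) and mitosis (0.15) calls. The ERK call also ended without P338 (-0.045), P522 (-0.14) or P530 (-0.063) or the ligand array of P524 (-0.11). The histone call ended without P522 (0.24) and the cholesterol call without the array of P530 lacking ligand (-0.22). Leaving out the ligand array of P524 also ended the mitosis and histone calls (adjusted p = 0.0523 each), that of P530 the mitosis call (0.0538) and that of P522 the histone call (0.0688). Array weights ended the cholesterol (-0.14), macrophage (-0.090) and NF-kappaB (-0.057) calls. The mitosis call was lost with no background correction (adjusted p = 0.05002), median scaling (0.0712), the authors' values (0.0565), no filter (0.0791) and the mean of probes (0.0508). The histone call was lost with no background correction (0.05002), the authors' values (0.0512) and no filter (0.0654). The ERK call was lost with median scaling (0.0937), no filter (0.0504), a stricter filter (0.0569), the mean of probes (0.0508) and only the groups compared (0.0547). Over all alternatives the adjusted p of these 7 lists went from 1.29e-10 to 0.961. The number of lists called was 3 without preparation P11 or the array of P530 lacking ligand, 4 without P338 or the ligand array of P524, and 13 without P393. All 7 calls held without P393, with larger means for mitosis (0.37), histones (0.27), G1/S (0.30) and ERK targets (-0.22). Without P522 the means were larger for mitosis (0.35) and NF-kappaB targets (-0.24), both called.

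With PDGF-B, Cd300ld was again lower in knockout cells, at 6.43 ± 0.34 against 9.13 ± 0.33 (SD, n = 3), a 6.50-fold difference (log2 change -2.70 ± 0.21 SE, adjusted p = 0.00228). Twistnb was lower as well, at 6.12 ± 0.22 against 7.46 ± 0.08, at least 2.52-fold, since 2 of 3 knockout arrays were above background (log2 change -1.34 ± 0.14 SE, adjusted p = 0.0127). These 2 genes were the only ones past the threshold, with 124 higher and 70 lower at an unadjusted p under 0.05, and the blocked fit called the same number. Both calls ended with median scaling (adjusted p = 0.0603 for Cd300ld and 0.293 for Twistnb), with only the groups compared in the fit (0.295 for each), and without preparation P11 (0.111 and 0.312) or P338 (0.0882 and 0.389), while log2 changes stayed at -2.70 to -2.76 and -1.33 to -1.40. Twistnb was also lost without preparation P393 (adjusted p = 0.238) or P530 (0.157) and without the array of P524 with ligand (-1.24, adjusted p = 0.0656). Over all alternatives that gave a p, the adjusted p went from 2.41e-04 to 0.295 for Cd300ld and from 3.88e-04 to 0.389 for Twistnb. The same preparations were used with and without ligand, so the genotype comparisons are not independent of each other.

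Cholesterol synthesis genes were lower in knockout cells with PDGF-B in 18 of 18 members (adjusted p = 1.16e-05, adjusted p = 0.987 with an estimated correlation), including Stard4 (-0.65 ± 0.29), Nsdhl (-0.74 ± 0.46) and Insig1 (-0.36 ± 0.27). Macrophage genes were lower in 16 of 19 (adjusted p = 0.00871, adjusted p = 0.987 with an estimated correlation), including Tyrobp (-0.56 ± 0.33) and Adgre1 (-0.46 ± 0.39). Genes of G1/S and replication were higher in 25 of 29, including Rrm2 (0.45 ± 0.26) and Mcm2 (0.14 ± 0.08), and those of mitosis in 22 of 24, including Kif2c (0.37 ± 0.25) but not Plk1 (-0.45 ± 0.33), each at adjusted p = 0.029. With an estimated correlation 0 of these 4 held (adjusted p = 0.987 for each with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The cholesterol call ended without preparation P522 (mean -0.019) and the macrophage call without P524 (0.030, the opposite sign) or P11 (-0.16), and array weights ended both (-0.12 and -0.049). Leaving out P11, P338, P524 or P530 each ended the calls of G1/S (0.0053, 0.11, 0.062 and 0.11) and of mitosis (0.070, 0.070, 0.052 and 0.059). Without P393 or P522 both calls held with larger means, at 0.25 and 0.19 for G1/S and 0.30 and 0.31 for mitosis. Median scaling (0.042), no filter (0.11) and array weights (0.14, adjusted p = 0.068) ended that of G1/S. No filter (0.11) and leaving out the array of P11 without ligand (adjusted p = 0.050007) ended that of mitosis, and the number of lists called was 7 without P393. Over all alternatives the adjusted p of these 4 lists went from 1.24e-10 to 0.997.

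**Figure D2:**
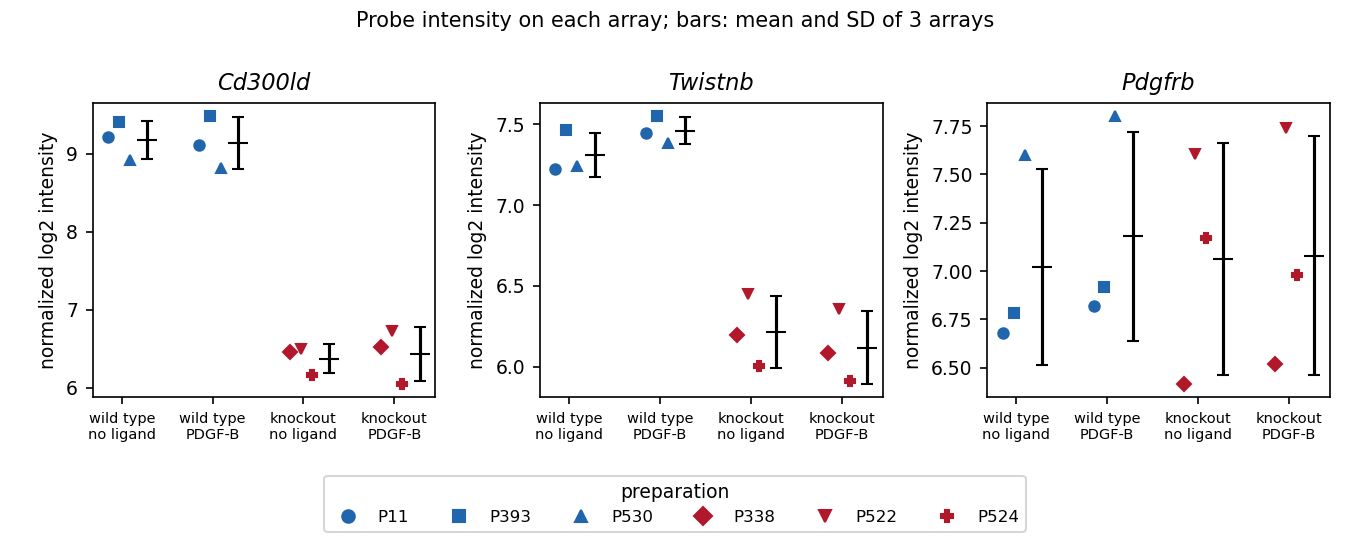
Normalized log2 intensity (y axis) of Cd300ld, Twistnb and Pdgfrb in the 4 groups (x axis), with 1 point per array, symbols for the numbered preparations, and bars for the mean and SD of 3 arrays. Cd300ld lies near 9.18 and 9.13 in wild-type and near 6.37 and 6.43 in knockout groups, while the genotypes overlap for Pdgfrb.

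In wild-type cells, 0 genes passed the threshold between PDGF-B and no ligand in limma. At an unadjusted p under 0.05 there were 40 higher and 39 lower, where chance gives 664, and with the preparation as a block 306 and 321, again with 0 past the threshold. The smallest p-values belonged to Chst11 (0.26 ± 0.08), Sgtb, Spata16, Gdap1l1 and Aifm1 on the positive side and to Cideb (-0.26 ± 0.06), Lap3, Rala, Zfp663 and Stox2 on the negative side. Timp1, an inhibitor of matrix metalloproteinases, differed by 0.37 ± 0.37 and Col1a1 by 0.38 ± 0.50, each positive in 3 of 3 pairs. Ccnd1 was at 0.19 ± 0.46, Egr1 at 0.05 ± 0.28, Fos at -0.09 ± 0.26, Acta2 at -0.01 ± 0.15 and Myc at 0.01 ± 0.07. For ligand changes, here and in the comparisons below, ± is the SE of the fit without a block. It includes level differences between preparations that cancel within pairs, so p-values of this fit can be too large. With the block, Timp1 averaged over both genotypes was at 0.36 ± 0.06. In a blocked fit without preparation P11, chosen after the data were seen, 146 genes passed (76 higher, 70 lower), against 0 when any other preparation was left out. That fit rests on P393 and P530 as the only wild-type pairs, with a spread shared with the knockout pairs.

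Of the gene lists, 3 rose with PDGF-B in the mean of the wild-type preparations. All 3 rose in P393 and P530 and fell in P11. The means in P11 were -0.056 for cholesterol synthesis, -0.13 for ribosome biogenesis and -0.084 for G1/S and replication. Cholesterol synthesis was positive in 18 of 18 members (mean 0.22, adjusted p = 0.00324, adjusted p = 0.949 with an estimated correlation), including Stard4 (0.38 ± 0.29) and Mvk (0.25 ± 0.22). Ribosome biogenesis was positive in 16 of 21 (0.09, adjusted p = 0.0325), including Srm, the spermidine synthase (0.41 ± 0.29), and Nhp2 (0.31 ± 0.21), and G1/S and replication in 21 of 29 (0.06, adjusted p = 0.048), including Ung (0.22 ± 0.08) and Mcm2 (0.17 ± 0.08). With an estimated correlation 0 of them held (adjusted p = 0.949 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. With the preparation as a block 7 lists were higher, adding fatty acid synthesis, matrix glycoproteins, amino acid stress response and fibrillar collagens, and 2 lower, p53 targets with cell-cycle inhibitors and mesothelial genes (adjusted p = 0.571 with an estimated correlation). All 3 calls ended without preparation P393 (cholesterol 0.11, ribosome biogenesis -0.011, G1/S 0.054) or P530 (0.19, 0.080 and -0.0027), which left 0 lists. They held without P11, where the means were larger (0.36, 0.20 and 0.14). The array of P11 without ligand ended the cholesterol (0.16) and G1/S (0.020) calls, and that of P522 the ribosome biogenesis (0.089, adjusted p = 0.0506) and G1/S (0.062, adjusted p = 0.0558) calls. G1/S was also lost without preparation P524 (adjusted p = 0.0785) and the array of P338 without ligand (0.0518), and turned negative without the ligand array of P393 (-0.064) or the array of P530 lacking ligand (-0.013, adjusted p = 0.93). The ligand array of P524 ended it too (adjusted p = 0.0573). Without the ligand array of P530 cholesterol synthesis was at 0.11 and ribosome biogenesis at 0.062, and without the array of P393 lacking ligand ribosome biogenesis was at 0.025, none of them called. The G1/S call was lost with median scaling (0.037), only the groups compared (adjusted p = 0.0658), an intensity trend and robust prior (0.0928) and array weights (0.0705). No filter ended the ribosome biogenesis call (0.078), and over all alternatives the adjusted p of the 3 lists went from 2.92e-15 to 0.975. The number of lists called was 7 without the ligand array of P11 or the array of P530 lacking ligand, 5 without the array of P393 lacking ligand, and 1 without that of P522.

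In knockout cells 0 genes passed between PDGF-B and no ligand in limma, with 62 higher and 71 lower at an unadjusted p under 0.05, and 0 with the block, where these numbers were 419 and 412. Tnc, the matrix protein tenascin C, had the smallest p among positive differences (0.96 ± 0.25, positive in 3 of 3 pairs), followed by Cog1, Tmed9, Farsb and Serp1, and Clrn3, Upk1a, Map1lc3a (-0.31 ± 0.09), Olfr1305 and Ccdc28a had the smallest among negative ones. Egr1, an immediate early gene, differed by 0.41 ± 0.28 and Timp1 by 0.35 ± 0.37, each positive in 3 of 3 pairs, Col1a1 by 0.31 ± 0.50 and Fos by -0.09 ± 0.26. A blocked fit without preparation P11, a wild-type one that enters through the shared spread, called 22 genes, all higher, against 1 without P338 and 0 without any other.

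Gene lists that rose with PDGF-B in knockout cells numbered 4. Ribosome biogenesis was positive in 18 of 21 members (mean 0.13, adjusted p = 4.27e-05, adjusted p = 0.556 with an estimated correlation), including Bop1 (0.47 ± 0.19) and Nop2 (0.17 ± 0.09). Chaperones of the endoplasmic reticulum were positive in 17 of 19 (0.10, adjusted p = 7.93e-04, adjusted p = 0.484 with an estimated correlation), including Hspa5 (0.42 ± 0.20) and Hyou1 (0.18 ± 0.09). ERK targets and feedback regulators were positive in 18 of 20 (0.13, adjusted p = 0.00129), including Dusp6 (0.18 ± 0.10) and Phlda1 (0.38 ± 0.31), and hypoxia and glycolysis genes in 17 of 21 (0.07, adjusted p = 0.0449), including Hk1 (0.18 ± 0.09) and Slc2a1 (0.26 ± 0.22). With an estimated correlation 0 held (adjusted p = 0.484 for ERK and 0.937 for hypoxia genes with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The block gave 11 higher lists, adding cholesterol and fatty acid synthesis, collagen processing, matrix glycoproteins, matrix remodelling, cytokines and chemokines, and hyaluronan and migration genes. It gave 1 lower list, the cell-cycle histones (adjusted p = 0.356 or more with an estimated correlation). Leaving out preparation P11, P338, P522 or P524 ended the hypoxia call (adjusted p = 0.0548, 0.0603, 0.063 and 0.152), where the array of P338 without ligand took the mean to -2.72e-04 and the ligand array of P522 to 0.0021. The ligand array of P524 ended the calls of ribosome biogenesis (0.083), chaperones (0.051) and ERK (0.073). The array of P338 without ligand ended those of ribosome biogenesis (0.071) and ERK (0.065). Calls also ended without the array of P522 lacking ligand for chaperones (0.066) and without its ligand array for ERK (0.10). Median scaling ended the chaperone (0.033) and hypoxia (0.015) calls and array weights those of chaperones (0.073), ERK (0.098) and hypoxia (0.070). The hypoxia call was also lost with no filter (adjusted p = 0.117), the mean of probes (0.182) and an intensity trend and robust prior (0.0893). Over all alternatives the adjusted p of the 4 lists went from 3.88e-07 to 0.937. The number of lists called was 2 without the ligand array of P524 and 13 without its other array.

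**Figure D3:**
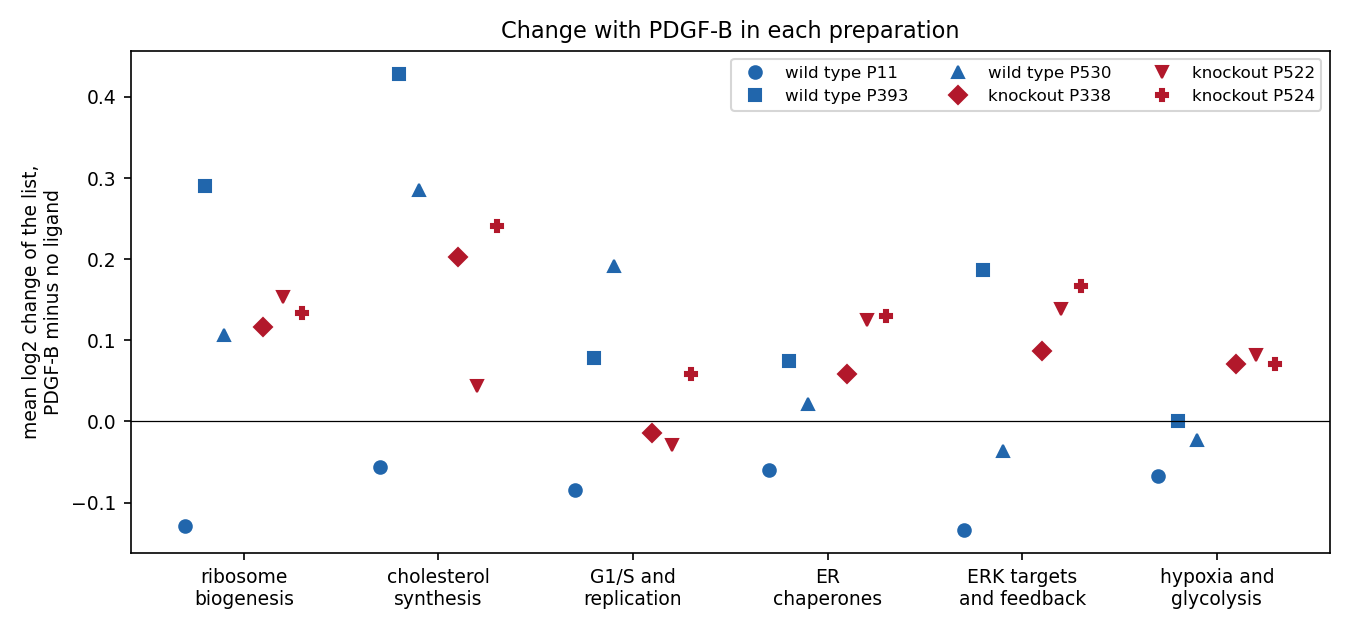
Mean log2 change with PDGF-B (y axis, ligand minus no ligand) of 6 gene lists (x axis), 1 point per preparation, in blue for the 3 wild-type and red for the 3 knockout preparations. Points of wild-type cells spread more widely than those of knockout cells for ERK targets and feedback (SD 0.16 against 0.04).

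Whether the response to PDGF-B depended on genotype was tested as the difference between the ligand changes. In limma 0 genes passed, with 37 higher and 43 lower at an unadjusted p under 0.05, and 0 with the block (269 and 329). Cul2 (0.41 ± 0.10), Lap3, Mblac2, Stox2 and Gpr141b had the smallest p among positive differences, and Map1lc3a (-0.54 ± 0.12), Pcbd2 (-0.48 ± 0.13), Scand1, Mrpl34 and Mrpl43 among negative ones. ERK targets and feedback regulators were the 1 list past the threshold, with a larger change in knockout than in wild-type cells (17 of 20 members, mean difference 0.13, adjusted p = 0.014), Dusp6 differing by 0.32 ± 0.14. That call did not hold with an estimated correlation (adjusted p = 0.988 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. It ended without preparation P11 (0.056), P522 (0.12), P524 (0.11) or P530 (0.10), without the arrays of P338 (0.059) and P530 (0.077) lacking ligand or the ligand array of P524 (0.067), with a stricter filter (0.14) and with array weights (0.095), at adjusted p from 1.68e-07 to 0.988 over all alternatives. The number of lists called was 4 without preparation P393, where the ERK difference was 0.22, and 5 without the ligand array of P338. With the block 5 lists differed (adjusted p = 0.476 or more with an estimated correlation). Besides ERK targets, mean ligand changes were 0.10 in knockout and 0.012 in wild-type cells for chaperones, 0.07 and -0.03 for hypoxia and glycolysis, -0.02 and -0.26 for mesothelial genes, and -0.09 and 0.05 for cell-cycle histones. The wild-type mean of mesothelial genes rested mainly on P530 (-0.59), against -0.18 in P393 and -0.0033 in P11. Timp1 (-0.02 ± 0.53), Col1a1 (-0.08 ± 0.70) and Egr1 (0.36 ± 0.39) did not differ past the threshold.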

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

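The tests of explanations in this part, the size minimums used in them and the splits by pairs were chosen after the results were seen.

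Targets and feedback regulators of ERK signalling changed more with PDGF-B in knockout than in wild-type cells, by 0.13 on the log2 scale (mean 0.13 against 0.0054, where the wild-type median was -0.011), by a test of the difference itself (adjusted p = 0.014). The call was lost with an estimated correlation (adjusted p = 0.988 with an estimated correlation) and without preparation P11 (0.056, adjusted p = 0.14). The list changed by -0.13 in P11, whose ligand change ran against the others, and by 0.19 in P393 and -0.04 in P530. The comparison shares its arrays without ligand with the genotype difference in which the same list was lower.

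Cd300ld was lower in knockout cells with and without ligand, and Twistnb with PDGF-B (without ligand its adjusted p was 0.0781). A smaller share of macrophages is argued against for Cd300ld: the macrophage list had a median difference of -0.25 (SD 0.23), and 0 of its 19 members reached 0.5 of the Cd300ld difference. This covers the macrophages as a whole, and a change in a subset or state of them was not tested. For Twistnb, a sequence difference under 1 probe stays open, because the other probe of the gene also differed (-1.44) but the positions of both are not known here. It stays open for Cd300ld too and could not be tested, since that gene had a single probe. A chromosome segment inherited with the Cre transgene, whose line has another strain background, may lie around either gene. A single segment cannot lie around both, as Cd300ld and Twistnb are on different chromosomes. Such a segment cannot be told apart from an effect of the deletion, since Cre and genotype coincide. Among the 20 nearest tested genes, 1 had an unadjusted p under 0.05 near each gene (35.3% of all genes have as many), and an effect of losing Pdgfrb was not tested separately.

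In wild-type preparation P11 the ligand change ran against that of the other 5 preparations (correlation across genes -0.30 with their mean, against 0.13 to 0.26 elsewhere). The choice among the normalizations tried is argued against, as the highest correlation under 3 other normalizations was -0.33. Of 97 genes that moved one way in all 5 others, with a mean change of at least 0.3, 17.5% moved that way in P11. For each other preparation the share was 76.5% to 100%, of only 11 to 20 genes. At minimums of 0.2, 0.4 and 0.5 the share was 20.1%, 22.5% and 25% in P11 against lowest values of 53.8%, 85.7% and 80% elsewhere, and among the 50 largest mean changes 24% against 78%. At these minimums the sets elsewhere held 47 to 93, 5 to 7 and 3 to 5 genes. Apart from the 50 largest, the sets elsewhere hold only genes on which P11 moved with the rest. These shares restate the negative correlation. Exchange of the arrays with and without ligand cannot be told apart from a real opposite change of those cells, which would give the same values, so both stay open and no label was changed. Mean array intensity rose with ligand in P11 (214 to 238) and fell in the other 5 preparations. Whether the ligand change is linked to array intensity was not tested.

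Gene lists called between the genotypes may rest on single preparations or on members varying together. Without P522 the cholesterol synthesis difference was -0.022 without ligand (adjusted p = 0.821, from -0.30) and -0.019 with PDGF-B (adjusted p = 0.672, from -0.36). Without P524 the macrophage difference was -0.014 without ligand (adjusted p = 0.961, from -0.27) and 0.030 with PDGF-B (adjusted p = 0.922, from -0.24). Allowing members to vary together, the smallest adjusted p of any list with an estimated correlation was 0.757 without ligand and 0.987 with PDGF-B. A true effect of genotype on these lists stays open and cannot be separated from preparations with 3 per genotype.

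Each comparison allows 10 splits of its samples, too few for a share under 0.05. As many genes as the real split were called by 10 splits for the ligand response in wild-type cells, in knockout cells and for their difference, where the real count and the highest other were all 0. For the genotype differences 1 split, the real one, reached its count (1 gene without ligand, 2 with PDGF-B, highest other 0). For lists, as many were called by 8 of 10 splits in wild-type cells (real 3, highest other 16), 7 in knockout cells (4 and 14), 7 between genotypes without ligand (7 and 13), 9 with PDGF-B (4 and 20) and 5 for the difference in response (1 and 4). Some splits called several times the real number of lists, which points to a structure of the samples, and the split with 16 lists parts only 1 of the 3 pairs. Among the 4 splits that part all pairs, the real one called 3 lists in wild-type cells (highest other 4) and 4 in knockout cells (0). With the preparation as a block, the real split called 0 genes and 9 lists in wild-type cells. The other splits that part all pairs exchange the ligand labels within 1 pair. They called 308 genes and 9 lists for P11, 0 genes and 10 lists for P393, and 0 genes and 4 lists for P530. The count for P11 restates its opposite ligand change. In knockout cells the real split called 0 genes (highest other 0) and 12 lists (highest other 3), and for the difference in response 5 lists (highest other 8).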

How the results depend on the processing

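The fits without each preparation that also use the preparation as a block were chosen after the data were seen, and the other alternatives before. Of 7688 values of 233 gene results under an alternative, 7656 stayed on their side of the threshold, 17 lost a call, 15 gained one and 0 reversed. Of 1261 values of 37 gene list results, 947 stayed, 165 lost a call, 141 gained one and 8 reversed. Direction was compared only where the main fit or the alternative made a call, so a change of sign without a call is not counted as reversed. Mesothelial genes in the difference in response, for example, went from -0.47 to 0.90 over the arrays and preparations left out. Signal over background limits the results, since 44.2% to 52.9% of probes were above background per array. Where a value below differs, the cause was not tested, except that leaving out samples leaves fewer of them. No slide was given in the sources used here, so the slide block was not run. The preparation as a block changed no call other than those given here and in the comparisons.

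With the preparation as a block the number of lists called was 9 for the ligand response of wild-type cells (3 without it), 12 for knockout cells (4) and 5 for the difference in response (1), and as a random block 2 for that difference. With an estimated inter-gene correlation it was 0 in all 5 comparisons. Median scaling gave 2 lists for the response of knockout cells and array weights 1, and for the difference in response the stricter filter and array weights each gave 0. With no filter on dim probes, 4 lists were called between the genotypes without ligand (7 with it) and 2 with PDGF-B (4 with it). Between the genotypes without ligand 2 genes (1 otherwise) were called with the mean of a gene's probes, with the preparation as a block (here the random block), with an intensity trend and robust prior, and with array weights. Counting only genes past the threshold with a log2 change of at least 1 left 1 gene between the genotypes without ligand, 2 with PDGF-B and 0 in the other comparisons, as without that minimum. With PDGF-B 0 genes (2 otherwise) were called with median scaling or with only the groups compared.

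Leaving out 1 array or preparation in turn gave 0 to 7 lists for the response of wild-type cells, 2 to 13 for knockout cells, 3 to 13 between genotypes without ligand, 3 to 7 with PDGF-B and 0 to 6 for the difference in response. Genes called numbered 0 to 3 between genotypes, without ligand and with PDGF-B alike, and 0 for both ligand responses and their difference, and the Pdgfrb difference went from -0.33 to 0.27. With the block and without P11, P338, P393, P522, P524 and P530 in this order, the number of lists was 9, 9, 9, 9, 9 and 7 in wild-type cells, 12, 10, 12, 8, 12 and 13 in knockout cells, and 5, 5, 7, 5, 7 and 2 for the difference. In the same fits 146 genes were called in wild-type cells and 22 in knockout cells without P11, and 1 in knockout cells without P338. Over these arrays and preparations the lists with a reversal went from -0.064 to 0.18 (G1/S) and -0.011 to 0.20 (ribosome biogenesis) in the response of wild-type cells. Between genotypes with PDGF-B they went from 0.0053 to 0.25 (G1/S) and -0.38 to 0.030 (macrophage genes). Reversed results were G1/S genes in the response of wild-type cells, at -0.064 without the ligand array of P393 and -0.0027 without P530 with the block, ribosome biogenesis there at -0.011 without P393 with or without the block. Others were macrophage genes between genotypes with PDGF-B at 0.030 without P524 or its ligand array, and G1/S genes there, whose mean stayed positive at 0.0053 without P11 or its ligand array while the test's direction turned.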

Other observations

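The averaged ligand response, its exact test and the fits without single preparations were chosen after the data were seen, as were the genes named here.

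Averaged over both genotypes with the preparation as a block, 0 of 13277 genes passed the threshold for PDGF-B in limma (860 at an unadjusted p under 0.05, smallest adjusted p = 0.117, and 124 at that level without the block). The smallest p-values belonged, in this order, to Spon2, a secreted matrix protein (0.79 ± 0.10 SE), Scd1, the stearoyl-CoA desaturase (0.59 ± 0.09), Glipr2 (0.28 ± 0.05), Col15a1 (0.51 ± 0.09), Bmp4 (-0.40 ± 0.07), Timp1 (0.36 ± 0.06), Foxs1 (0.28 ± 0.05) and Cd248 (0.26 ± 0.05). Bmp4 was negative and the others positive in 6 of 6 pairs. By camera 14 lists were higher, led by cholesterol synthesis (mean 0.19, positive in 5 of 6 pairs) and ribosome biogenesis (0.11, 5 of 6), and 3 were lower, namely mesothelial genes (-0.14), p53 targets with cell-cycle inhibitors (-0.06) and interferon response genes (-0.05). With an estimated correlation 0 held (adjusted p = 0.232 or more with an estimated correlation). The mean of mesothelial genes rested mainly on P530 (-0.59), with the other preparations between -0.18 (P393) and 0.05 (P522). In an exact sign-flip test over the 6 pairs, 4 lists reached the smallest p it can give, 0.03125, and the smallest adjusted value over 39 lists was 0.305. These 4 were fatty acid synthesis and hyaluronan and migration genes, higher in 6 of 6 pairs, and p53 targets with cell-cycle inhibitors and interferon response genes, higher in 0 of 6.

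Without preparation P11 the averaged response held 69 genes higher and 21 lower, and 0 without any other preparation. Because P11 was left out after its discordance was seen, these p-values are too small to be taken at face value. Of these 90 genes 76 had the opposite sign in P11 and 14 the same. Opposite in sign were Tnc (0.93 ± 0.09), Fgf7, a growth factor of epithelial cells (0.67 ± 0.06), Cd44, the hyaluronan receptor (0.58 ± 0.05), Bcat1 (0.82 ± 0.08) and Socs2 (0.51 ± 0.06), at -0.06, -0.20, -0.19, -0.31 and -0.58 in P11. The same in sign were Spon2 (0.90, and 0.25 in P11), Scd1 (0.64 and 0.33), Glipr2 (0.29 and 0.28) and Timp1 (0.35 and 0.38), among others. In the blocked fit without P11, P393 and P530 were the only wild-type pairs, and the spread came from the knockout pairs as well. Prl2c3 (1.57 ± 0.14) and Srm (0.78 ± 0.07) were higher there with ligand in wild-type cells. Slc40a1, the iron exporter, was lower (-0.86 ± 0.16). In P11 itself these genes were at -0.48, -0.34 and 0.11. Of the 146 genes called in that fit 119 had the opposite sign in P11 and 27 the same. Of sign patterns over the 6 pairs, 471 genes went one way in all pairs as labelled, a count that 8 of the 32 patterns reach, this one included, where chance gives 415. With the sign of pair P11 turned 1007 did so, the highest count. Ligand changes correlated across genes at 0.03 to 0.30 in the 10 combinations of preparations without P11 and at -0.39 to -0.02 in those with it. Genes are not independent replicates in these correlations. Mean intensity went from 214 to 238 with ligand in P11 and was lower with ligand in the other 5.

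Among the 4470 kept probes without a single gene symbol, 0 passed the threshold in any of the 5 comparisons in limma, and 46, 84, 153, 105 and 55 had an unadjusted p under 0.05 in the ligand response of wild-type and knockout cells, the genotype difference without and with ligand, and the difference in response.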
